A study of Mus musculus with 12 samples.

How the data were processed

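RNA from 12 libraries of sorted mouse thymic epithelial cells (TECs) was compared: cortical TECs (cTECs) and medullary TECs with high MHC class II (mTEChi), each from Foxn1-Cre carriers with floxed Hoil (HOIL-deficient) and from floxed mice without Cre (control), 3 libraries per group. Per the labels' protocols, cells were sorted by flow cytometry as CD45-negative, TER119-negative, CD31-negative and EpCAM-positive cells, with Ly51 marking cTECs and UEA1 lectin with high MHC class II marking mTEChi. Libraries were made with a low-input SMART-Seq kit and Nextera XT and sequenced in paired ends on an Illumina NextSeq instrument. Per the submitters' processing notes, reads were assigned to genes with featureCounts on the mm10 build. The aligner, the annotation release, the tool versions and the strandedness are not given in the sources used here, so overlapping antisense pairs such as Xist and Tsix cannot be told apart.

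The deposited files hold 1 raw count per gene for each library, with the gene length, for 27179 genes identified by Entrez ID. Symbols, chromosomes and positions came from a RefSeq table of GRCm38.p6, the assembly that mm10 names. A symbol matched 25275 IDs, and the other 1904 held 4.53 to 6.10% of the counts of a library. The deposited table that joins all libraries was left out because each library has its own file. Totals ranged from 7941217 to 14274333 counts per library. A group whose libraries were all at 0 was read as up to 3 counts over the group, which is 0.105 CPM (counts scaled to the library total) in control cTECs, 0.0889 in HOIL-deficient cTECs, 0.113 in control mTEChi and 0.0867 in HOIL-deficient mTEChi. Folds against such a group are lower bounds. A ratio against a group with 1 to 3 counts has an exact 95% interval. These floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

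Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr on the 4 groups, which left 19398 tested genes, 18413 of them with a symbol. Libraries were scaled by TMM, and all 12 were fitted together with 1 coefficient per group by the robust quasi-likelihood method of edgeR. Each comparison used its quasi-likelihood F test, and adjusted p values are Benjamini-Hochberg values over the tested genes, called under 0.05. Fold changes are log2 values made with the default prior count of edgeR, and levels are CPM as mean ± SD of the 3 libraries of a group. The standard error (SE) given with a fold change is approximate: its absolute value divided by the square root of the F statistic. It is least reliable for groups near 0, where the prior count alters the fold change most. The 4 comparisons were HOIL deficiency in cTECs, HOIL deficiency in mTEChi, the difference between these effects (the mTEChi effect minus the cTEC effect, an interaction contrast) and control mTEChi against control cTECs. No replicate block and no sex term was used: the labels do not say that a replicate number marks 1 animal or day, and the 2 female libraries are replicate 3 of both HOIL-deficient groups. The labels do not say that replicates are separate animals either, so p values measure the spread between these samples.

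The comparisons, the tests, the alternatives and 28 gene lists were fixed before the data were examined. The lists covered LUBAC and its deubiquitinases, NF-kB target genes, the TNF receptor family with NIK signalling, apoptosis and necroptosis machinery, p53 target genes, interferon-stimulated genes, MHC class II and class I presentation, cTEC-associated and mTEC-associated genes, Aire-dependent tissue-restricted genes, tuft, keratinized and other mimetic cell genes, cell cycle, immediate early and dissociation stress genes, the unfolded protein response, glycogen metabolism, Notch and Wnt pathway genes, oxidative phosphorylation, ribosomal proteins, sex-linked check genes and markers of thymocytes, B and plasma cells, dendritic cells and macrophages, fibroblasts and pericytes, endothelial cells and erythroid cells. Lists were tested with camera (limma) at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. For each list the members past the test over all genes were counted, and those past it when adjusted over the list alone.

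Genes were named by a rule: Rbck1, Rnf31 and Sharpin; the 8 higher and 8 lower genes with the largest log2 fold change among called genes with a mean of at least 1 log2 CPM, no overlap between the groups' libraries and a symbol that is not sex-linked, predicted or a pseudogene; up to 4 members of each list with the smallest p; and Foxn1, Psmb11, Prss16, Ly75, Dll4 and Ccl25 for cTECs or Aire, Fezf2, Cd80, Tnfrsf11a, Ccl21a and H2-Aa for mTEChi. The difference and the cell type comparison took 5 genes per direction, and only the difference left out the no-overlap rule. Single measures of the libraries were compared by 2-sided exact permutation tests, for which 3 against 3 libraries cannot give a p under 0.1.

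Alternatives were RLE and upper-quartile scaling, no filter on low counts, CPM over 1 in at least 3 libraries, DESeq2 1.42.0, limma-voom with quality weights, a fit of only the groups compared, a fit without robust estimation, a replicate block, a sex covariate, males only, and each library left out in turn. Added after the data were seen were the LUBAC list without Rbck1, a fit without both control libraries numbered 1 and a fit with the trends on gene length and GC content removed in each library. In simulated data made from these libraries with the dispersions of edgeR, 100 genes were changed 2-fold and 100 were changed 4-fold per comparison. These are fewer than were called in the real data, which makes the adjusted threshold stricter. The shares below therefore need not hold for the real data. Of these genes, edgeR recovered 32 and 72% in cTECs, 30 and 86% in mTEChi, 0 and 45% for the difference and 25 and 85% between cell types. Differences of 2-fold between the effects may thus be missed by edgeR. Its false calls were 6.09, 5.65, 0 and 4.31% of calls in the same order. Those of DESeq2 were 13.8 to 22.7% and those of limma-voom 4.95 to 13.9%.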

Results

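Thymic epithelial cells are the stromal cells that guide and select developing T cells. Their RNA was sequenced in 12 libraries from C57BL/6 mice, 3 each of control cTECs, HOIL-deficient cTECs, control mTEChi and HOIL-deficient mTEChi. HOIL-1, encoded by Rbck1, is a subunit of LUBAC, the complex that builds linear ubiquitin chains in TNF receptor family signalling. Total counts of replicates 1 to 3 were 10858804, 7941217 and 9681076 in control cTECs and 8445145, 9759586 and 13259887 in HOIL-deficient cTECs. They were 9768040, 9669907 and 8641463 in control mTEChi and 10137044, 10706459 and 14274333 in HOIL-deficient mTEChi. The first principal component, with 76.9% of the variance, separated the cell types. Xist was at 136 to 166 CPM in the 2 libraries labelled female and at 1.52 to 7.83 CPM in the 10 labelled male.

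RNA composition differed between the mTEChi groups. Mitochondrial transcripts made up 5.49 ± 3.03% of counts in control mTEChi, with 8.93% in replicate 1, against 1.84 ± 0.113% in HOIL-deficient mTEChi (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). The nuclear RNA Malat1 took 4.13 ± 0.931% against 0.851 ± 0.135% (exact permutation p = 0.1). In cTECs the mitochondrial share was 1.13 ± 0.279% in controls and 1.46 ± 0.352% in HOIL-deficient libraries (exact permutation p = 0.4). Fewer genes were detected in HOIL-deficient libraries of both cell types when every library was thinned to the smallest total. In cTECs 17252 ± 317 genes had a count against 17969 ± 101 in controls (exact permutation p = 0.1). In mTEChi there were 21401 ± 423 against 22803 ± 609 (exact permutation p = 0.1).

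Rbck1 (Entrez 24105, chromosome 2, 152316334 to 152332663), the targeted gene, fell in both HOIL-deficient populations. In cTECs it went from 212 ± 25.1 to 24.2 ± 6.10 CPM (log2 fold change -3.13, SE 0.271, adjusted p = 2.8e-05), and in mTEChi from 124 ± 9.69 to 15.5 ± 6.86 CPM (-2.99, SE 0.272, adjusted p = 4.5e-05). Here and below n = 3 libraries per group, levels are mean ± SD and changes are log2 fold changes. The 2 effects did not differ detectably (difference 0.14, SE 0.360, adjusted p = 0.88). Sharpin (Entrez 106025, chromosome 15, 76347040 to 76351110), another LUBAC subunit, fell in cTECs from 68.1 ± 15.3 to 44.5 ± 5.04 CPM (-0.61, SE 0.181, adjusted p = 0.041). That call was lost without any cTEC library other than control replicate 2 (adjusted p 0.052 to 0.14, and 0.019 to 0.14 over all alternatives). In mTEChi, Sharpin stood at 41.3 ± 1.09 and 42.7 ± 2.15 CPM (adjusted p = 0.88). Rnf31 (Entrez 268749, chromosome 14, 55591713 to 55603674), which encodes the catalytic subunit HOIP, had a log2 fold change of -0.98 (SE 0.323, adjusted p = 0.063) in cTECs and -0.96 (SE 0.322, adjusted p = 0.049) in mTEChi. The cTEC value passed without control replicate 1 (adjusted p = 0.018, within 0.017 to 0.25 over all alternatives). The mTEChi value failed when any single mTEChi library was left out (adjusted p 0.063 to 0.17, within 0.012 to 0.17 over all alternatives).

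**Figure D1:**
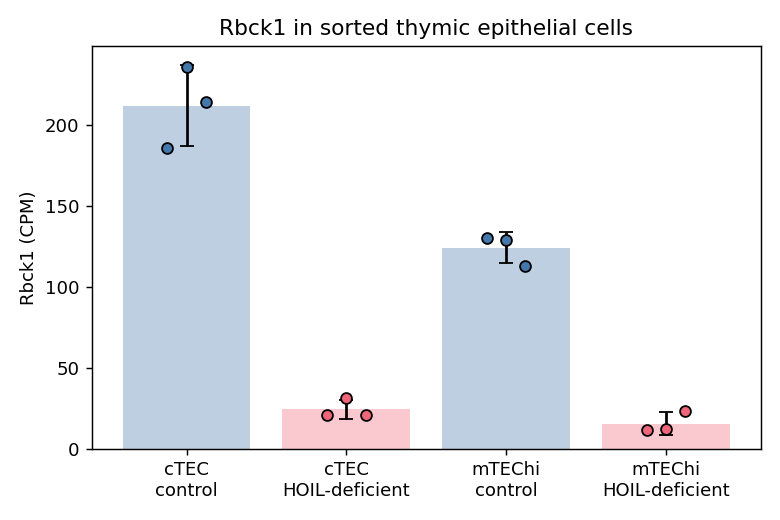
Rbck1 in CPM by group, with bars for the mean, error bars for the SD and 1 point per library (n = 3 per group). HOIL-deficient means were 24.2 CPM in cTECs and 15.5 CPM in mTEChi, against 212 and 124 CPM in the controls.

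HOIL-deficient cTECs were compared with control cTECs to show which genes change in the cortical compartment. They held less RNA of 5 of the 6 cTEC genes chosen in advance. Prss16 (Entrez 54373, chromosome 13, 22002176 to 22009741), a thymus-specific serine protease, fell from 10773 ± 931 to 4303 ± 245 CPM (-1.32, SE 0.251, adjusted p = 0.0045). Psmb11 (Entrez 73902, chromosome 14, 54625310 to 54629556), the thymoproteasome subunit beta5t, fell from 3772 ± 624 to 1476 ± 109.6 CPM (-1.35, SE 0.201, adjusted p = 0.0011). The endocytic receptor Ly75 (Entrez 17076, chromosome 2, 60292103 to 60383273) fell from 687 ± 116 to 248 ± 28.9 CPM (-1.47, adjusted p = 0.0015). The Notch ligand Dll4 (Entrez 54485, chromosome 2, 119325784 to 119335666) fell by 1.13 on the log2 scale (SE 0.236, adjusted p = 0.0081), and the chemokine Ccl25 (Entrez 20300, chromosome 8, 4325205 to 4360020) fell by 0.89 (SE 0.185, adjusted p = 0.0074). For each of these 5 genes the control and HOIL-deficient libraries did not overlap, which chance alone gives for 10% of genes. Foxn1 (Entrez 15218, chromosome 11, 78357577 to 78386783), the transcription factor that specifies TECs, was at 515 ± 152 and 337 ± 55.7 CPM and missed the threshold (-0.61, SE 0.258, adjusted p = 0.14). It passed without control replicate 1 (adjusted p = 0.048, within 0.0089 to 0.43 over all alternatives).

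The list of cTEC-associated genes fell as a group. Of its 29 tested members 11 fell and 1 rose (12 and 1 adjusted over the list alone), with a median log2 fold change of -0.51 (adjusted p = 7.5e-07, camera with the preset correlation). With an estimated correlation the list had adjusted p = 0.27. Cd83, which stabilises MHC class II at the cTEC surface, fell from 3801 ± 904 to 958 ± 80.9 CPM (-1.99, SE 0.265, adjusted p = 0.00054). The endocytosis adaptor Snap91 fell by 1.85 (SE 0.164, adjusted p = 3.0e-05), and Cd274, which encodes the inhibitory ligand PD-L1, fell from 428 ± 31.8 to 155 ± 16.8 CPM (-1.47, SE 0.137, adjusted p = 4.8e-05).

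Interferon-stimulated genes also fell in cTECs. Of 45 members 13 fell and none rose (15 and 0 adjusted over the list alone). The median was -0.47 (adjusted p = 3.2e-06, but adjusted p = 0.47 with an estimated correlation). The exonuclease Isg20 fell from 1774 ± 255 to 960.1 ± 88.1 CPM (-0.89, adjusted p = 0.0020), and the deISGylase Usp18 fell too (-0.97, adjusted p = 0.0033). Ifit3b had a log2 fold change of -1.40, a value that its close paralog Ifit3 makes uncertain. LUBAC and its deubiquitinases had 3 of 10 members lower and none higher (5 and 0 adjusted over the list alone). Their median was -0.44 (adjusted p = 0.00034, but adjusted p = 0.19 with an estimated correlation). That list holds the targeted gene Rbck1. Without Rbck1, 2 of 9 members were lower and none higher (4 and 0 adjusted over the list alone), and the median was -0.37 (adjusted p = 0.049, but adjusted p = 0.27 with an estimated correlation). The NF-kB target list had 1 of 42 higher and 6 lower (2 and 9 adjusted over the list alone) and did not pass (adjusted p = 0.080). It passed without control replicate 1 (adjusted p = 0.0053, within 0.0014 to 0.67 over all alternatives). Its member Irf1, an interferon and NF-kB regulated transcription factor, fell from 891 ± 65.4 to 536 ± 41.4 CPM (-0.73, SE 0.131, adjusted p = 0.0034). MHC class II presentation had 0 of 22 higher and 5 lower (1 and 5 adjusted over the list alone). It did not pass as a list (adjusted p = 0.095), except by fry (adjusted p = 0.033) and with length and GC trends removed (median -0.25, adjusted p = 0.023). MHC class I presentation had 2 of 22 higher and 2 lower (4 and 4 adjusted over the list alone) and did not pass either (adjusted p = 0.77). Ifi30, the lysosomal thiol reductase of class II presentation, fell by 0.80 (SE 0.141, adjusted p = 0.0030).

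Several genes that mark other TEC states rose in HOIL-deficient cTECs. Krt14, a basal keratin, rose from 48.7 ± 16.9 to 323 ± 55.6 CPM (2.73, SE 0.239, adjusted p = 2.8e-05), and the chemokine Ccl19 rose by 1.83 (SE 0.204, adjusted p = 0.00017). Utf1, a transcription factor of undifferentiated cells, rose from 1.70 ± 0.268 to 13.9 ± 1.63 CPM (3.02, SE 0.185, adjusted p = 2.7e-06). Their list of mTEC-associated genes went both ways, with 7 of 33 higher and 8 lower (7 and 9 adjusted over the list alone, adjusted p = 0.70). Hspa5, a chaperone of the endoplasmic reticulum, rose from 806 ± 5.68 to 1446 ± 68.5 CPM (0.84, SE 0.163, adjusted p = 0.0051) and the disulfide isomerase Pdia6 from 204 ± 12.2 to 422 ± 28.5 CPM (1.05, SE 0.130, adjusted p = 0.00033). The unfolded protein response list had 7 of 29 higher and 3 lower (8 and 5 adjusted over the list alone) and did not pass (adjusted p = 0.29). Ribosomal proteins had 4 of 39 higher and none lower (5 and 0 adjusted over the list alone) and passed with a median of 0.47 (adjusted p = 3.2e-06). That list had adjusted p = 0.67 with an estimated correlation and 0.13 by fry (2.1e-08 to 0.67 over all alternatives).

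Markers of other cell types moved apart in the same cTEC libraries. Endothelial genes rose, with 15 of 20 higher and none lower (17 and 1 adjusted over the list alone). Their median was 2.70, or 2.64 with genes at 0 set to their bound (adjusted p = 4.7e-13, but adjusted p = 0.27 with an estimated correlation). Kdr, the VEGF receptor, rose from 0.788 ± 0.469 to 18.0 ± 10.03 CPM (4.50, SE 0.710, adjusted p = 0.0016), and the endothelial transcription factor Sox18 rose by 2.83 (SE 0.400, adjusted p = 0.00079). Fibroblast and pericyte genes rose, with 10 of 25 higher and none lower (14 and 1 adjusted over the list alone). Their median was 1.50 (adjusted p = 3.5e-09, but adjusted p = 0.27 with an estimated correlation), and it ran from 1.10 to 2.49 over all alternatives. The mean log2 CPM of this list was 5.21 in control replicate 1, against 2.68 and 4.12 in the other controls and 5.33 to 6.09 in HOIL-deficient cTECs. Acta2, smooth muscle actin, went from 69.2 ± 48.5 to 764 ± 270.0 CPM (3.46, SE 0.561, adjusted p = 0.0023). Thymocyte genes fell, with 19 of 23 lower and none higher (23 and 0 adjusted over the list alone). Their median was -1.89 (adjusted p = 4.7e-13, but adjusted p = 0.39 with an estimated correlation). Lck, the kinase of T cell receptor signalling, went from 545 ± 329 to 137 ± 55.7 CPM (-1.99, SE 0.369, adjusted p = 0.0041) and Cd4 from 88.2 ± 21.6 to 22.4 ± 12.1 CPM (-1.97, SE 0.388, adjusted p = 0.0056). The mean log2 CPM of the thymocyte list was 7.46 in control replicate 1, against 5.72 and 6.23 in the other controls and 4.42 to 5.29 in HOIL-deficient cTECs. It moved in the same direction as the cTEC-associated genes above.

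**Figure D2:**
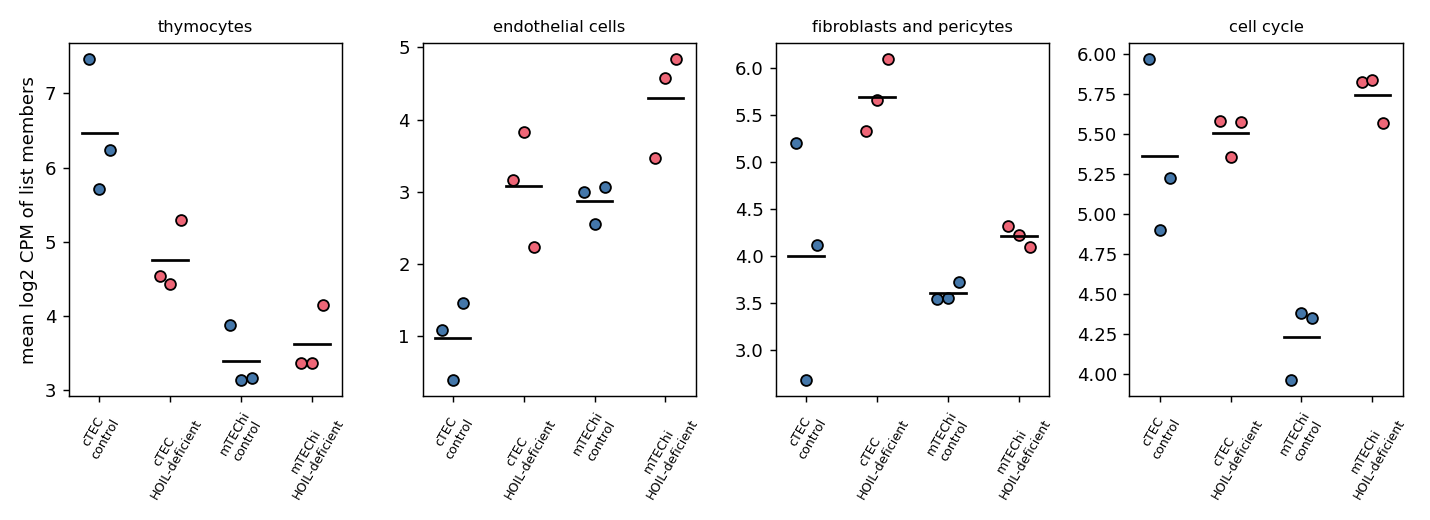
Mean log2 CPM over the tested members of the thymocyte, endothelial, fibroblast and pericyte, and cell cycle lists in each library, with 1 point per library and a line at the group mean (n = 3 per group). The endothelial score was 2.23 to 3.82 in HOIL-deficient cTECs against 0.389 to 1.46 in control cTECs, and the cell cycle score 5.57 to 5.84 in HOIL-deficient mTEChi against 3.96 to 4.38 in control mTEChi.

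Among the largest increases in cTECs, Cfd, the adipocyte protease adipsin, rose from 0.125 ± 0.216 to 104 ± 34.7 CPM (9.42, SE 1.03, adjusted p = 0.00018). Car3, a carbonic anhydrase, rose from 1.03 ± 1.29 to 121 ± 98.5 CPM (6.99, SE 0.781, adjusted p = 0.00021), and the hormone gene Adipoq from 0.251 ± 0.435 to 15.8 ± 6.59 CPM (6.13, SE 0.749, adjusted p = 0.00030). Against 1 to 3 control counts, the ratio was 122 for the adipocyte hormone Retn (95% interval 21.6 to 4857), 96.7 for the lipid droplet protein Cidec (32.8 to 471) and 59.4 for the retinol carrier Rbp4 (10.3 to 2378). The mucin-like Dmbt1 was at least 17.9-fold higher and Itih3 at least 11.6-fold higher, both at 0 in control cTECs. The 8 largest decreases were all at 0 in HOIL-deficient cTECs. Their bounds are multiples of the 0.0889 CPM floor, so these genes were at low levels in control cTECs too. The level filter took the mean over all 12 libraries, so a gene could pass it through its level in mTEChi. The transporter Slco4a1 was at least 35.9-fold lower, the flippase Atp8b4 at least 20.8-fold, Paqr5 at least 17.9-fold and the cadherin Cdh9 at least 16.9-fold lower. The cytokine receptor Il9r was at least 13.2-fold lower, Cldn13 at least 11.3-fold, Slc10a4 at least 9.82-fold and Calca at least 9.50-fold lower. Itih3 lost its call without HOIL-deficient replicate 3 (adjusted p = 0.083) or without control replicate 1, 2 or 3 (adjusted p 0.060, 0.060 and 0.074), and Cldn13 among males only (adjusted p = 0.053).

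Other lists did not pass in cTECs by camera with the preset correlation and all libraries. Their members past the test are given as higher and lower over all genes, then adjusted over the list alone. The TNF receptor family with NIK signalling had 1 and 3 of 25 (1 and 3 adjusted over the list alone, adjusted p = 0.32). Apoptosis and necroptosis machinery had 1 and 1 of 31 (1 and 0 adjusted over the list alone, adjusted p = 0.70) and passed only by fry (adjusted p = 0.047). Of 29 p53 target genes 5 were higher and 1 lower (5 and 1 adjusted over the list alone, adjusted p = 0.095), and the kinase Plk2 rose by 2.18 (SE 0.363, adjusted p = 0.0022). The p53 list passed only by fry (higher, adjusted p = 0.0040). Aire-dependent genes had 0 and 3 of 54 (0 and 2 adjusted over the list alone, adjusted p = 0.69). Keratinized cell genes had 3 and 6 of 32 (5 and 6 adjusted over the list alone, adjusted p = 0.92), and other mimetic cell genes 3 and 3 of 44 (3 and 3, adjusted p = 0.70). Tuft cell genes had 3 higher and 1 lower of 28 (3 and 6 adjusted over the list alone, adjusted p = 0.70), and their median moved from -1.32 to -0.65 with genes at 0 set to their bound. Cell cycle genes had 5 and 0 of 42 (5 and 0 adjusted over the list alone, adjusted p = 0.18). The cell cycle median was -0.04, but without control replicate 1 it was 0.35 and the list passed (adjusted p = 5.4e-07, within 5.5e-08 to 0.88 over all alternatives). B and plasma cell genes had 1 and 4 of 15 (1 and 6 adjusted over the list alone, adjusted p = 0.23). They passed without control replicate 2 (adjusted p = 0.039, within 0.039 to 0.67 over all alternatives). Dendritic cell and macrophage genes had 1 and 1 of 23 (1 and 1, adjusted p = 0.38), and erythroid genes 0 and 1 of 10 (0 and 1, adjusted p = 0.79). Immediate early and dissociation stress genes had 2 and 1 of 29 (2 and 1, adjusted p = 0.32), and glycogen metabolism 2 and 1 of 25 (2 and 1, adjusted p = 0.59). Notch and Wnt pathway genes had 5 and 5 of 29 (9 and 9, adjusted p = 0.76). Oxidative phosphorylation had 0 and 1 of 33 (0 and 0, adjusted p = 0.70) and the sex-linked check genes 0 and 0 of 7 (0 and 0).

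In all, 2342 of 19398 genes changed in HOIL-deficient cTECs (12.1%; edgeR), 1175 higher and 1167 lower, of which 950 and 753 changed at least 2-fold. The even balance moved with the scaling, to 1274 higher and 959 lower with RLE factors and 1301 and 915 with upper-quartile factors. It went the other way with limma-voom, to 1805 higher and 2065 lower. The count was 1340 without control replicate 3 and 1445 without HOIL-deficient replicate 2.

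HOIL-deficient mTEChi were compared with control mTEChi to show which genes change in the medullary compartment. They held less RNA of tissue-restricted genes, while the regulators of those genes did not change detectably. Aire (Entrez 11634, chromosome 10, 78030022 to 78043610), which drives tissue-restricted genes, was at 811 ± 159 and 943 ± 131 CPM (0.22, SE 0.352, adjusted p = 0.71), and Fezf2 (Entrez 54713, chromosome 14, 12338992 to 12346803), another such regulator, at 369 ± 22.8 and 630.1 ± 60.6 CPM (0.77, SE 0.383, adjusted p = 0.17). Fezf2 passed with limma-voom (adjusted p = 0.0010) and in a fit of only the mTEChi groups (0.0039; 0.0010 to 0.58 over all alternatives). The list of Aire-dependent tissue-restricted genes fell, with 16 of 54 lower and none higher (22 and 1 adjusted over the list alone). Its median was -1.15 (adjusted p = 7.7e-10), and the call held with an estimated correlation (adjusted p = 0.023). Fabp9, a testis fatty acid binding protein, fell from 227 ± 127 to 33.9 ± 7.88 CPM (-2.74, SE 0.373, adjusted p = 0.00049). Klk1b26 had a log2 fold change of -2.66 (adjusted p = 0.00013), but the kallikrein family is so alike in sequence that its member values are uncertain.

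Genes of the mimetic cells, medullary cells that resemble peripheral tissues, also fell. Tuft cell genes had 13 of 28 lower and none higher (14 and 0 adjusted over the list alone). Their median was -1.45 (adjusted p = 1.0e-05, but adjusted p = 0.14 with an estimated correlation). Pou2f3, the tuft cell transcription factor, went from 45.3 ± 16.8 to 11.99 ± 4.06 CPM (-1.91, SE 0.423, adjusted p = 0.0072). Keratinized cell genes had 14 of 32 lower and none higher (17 and 1 adjusted over the list alone). Their median was -1.03 (adjusted p = 1.0e-05, but adjusted p = 0.056 with an estimated correlation). Krt10, a keratin of cornifying epidermis, went from 56.4 ± 38.3 to 9.66 ± 4.31 CPM (-2.54, SE 0.416, adjusted p = 0.0014). Other mimetic cell genes had 15 of 44 lower and none higher (17 and 0 adjusted over the list alone). Their median was -0.81 (adjusted p = 2.4e-05, but adjusted p = 0.056 with an estimated correlation). The cell surface mucin Muc13 fell (-2.21, SE 0.261, adjusted p = 0.00036), as did the cilium gene Dynlrb2 (-3.39, SE 0.670, adjusted p = 0.0039). The taste receptor Tas2r105 had 256 counts in controls and 1 in HOIL-deficient libraries, a ratio of 335 (95% interval 59.6 to 13280.0). These lists, like the other mTEChi changes given below, went with the mitochondrial and Malat1 shares, which were lower in the same 3 HOIL-deficient libraries.

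**Figure D3:**
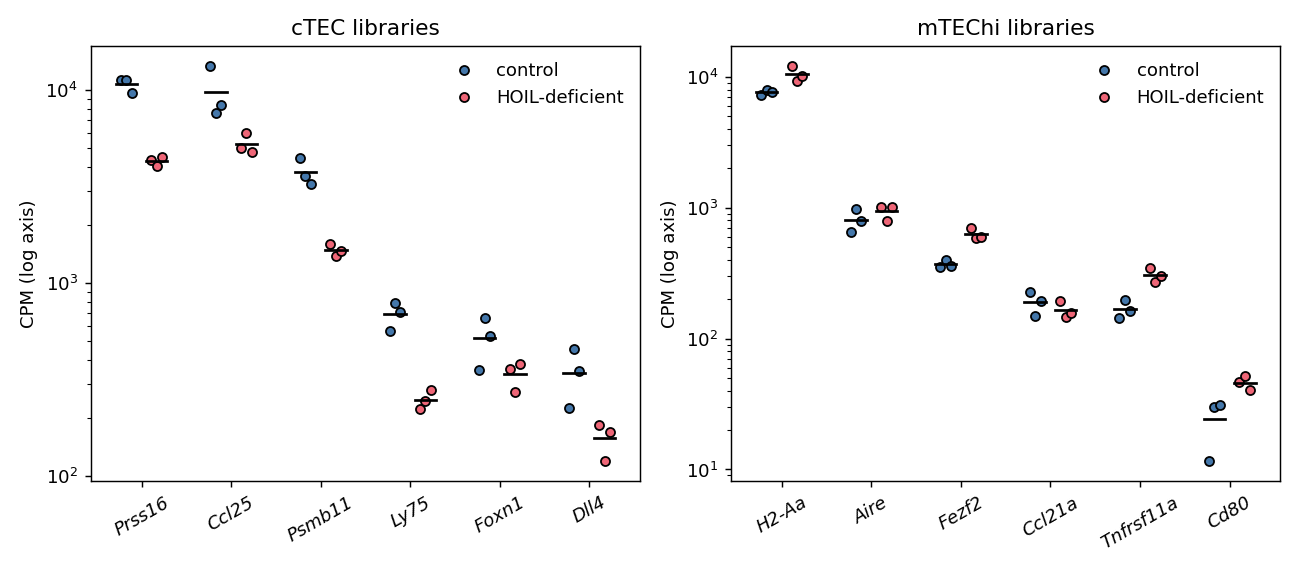
CPM on a log axis of 6 cTEC genes in cTEC libraries and of 6 mTEC genes in mTEChi libraries, with 1 point per library and a line at the group mean (n = 3 per group). Psmb11 went from 3772 to 1476 CPM in cTECs, and Aire was at 811 and 943 CPM in mTEChi.

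Among the largest decreases in mTEChi, the immunoglobulin transporter Pigr fell from 129 ± 78.8 to 5.39 ± 5.53 CPM (-4.54, SE 0.817, adjusted p = 0.0028). The trypsin inhibitor Spink1 fell from 135 ± 99.2 to 6.40 ± 2.72 CPM (-4.38, SE 0.606, adjusted p = 0.00086) and Spink5, the protease inhibitor of the epidermis, from 171 ± 56.2 to 16.8 ± 3.12 CPM (-3.34, SE 0.531, adjusted p = 0.0012). Dapl1 (-3.25), Smim6 (-3.36) and the cilium gene Ccdc153 (-4.05) fell as well, and the kallikrein Klk1b16 had a log2 fold change of -3.54. The sodium channel gene Scn1a had 23 counts against 2, a ratio of 15.1 (95% interval 3.72 to 132), and lost its call without HOIL-deficient replicate 1, 2 or 3 (adjusted p 0.063, 0.050 and 0.055) or control replicate 1 (adjusted p = 0.13). The largest increases were in Cdh19, a cadherin of Schwann cells, from 0.265 ± 0.245 to 9.52 ± 4.54 CPM (5.10, SE 0.697, adjusted p = 0.00049), the Wnt receptor Fzd4 (4.69), the endothelial lectin Clec14a (3.96), Aspa (3.87), Lrg1 (3.77, SE 0.498, adjusted p = 0.00041) and the homeobox gene Meox2 (3.61). Abca8b rose from 0.174 ± 0.301 to 2.75 ± 0.921 CPM (3.80, SE 0.857, adjusted p = 0.0079). The fatty acid transporter Cd36 rose by 3.79 on the log2 scale, but not without control replicate 1 or 2 (adjusted p 0.061 and 0.054; at most 0.091 over all alternatives).

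Cell cycle genes rose in HOIL-deficient mTEChi. Of 42 members 37 were higher and none lower (39 and 0 adjusted over the list alone). Their median was 1.54 (adjusted p = 3.4e-26, but adjusted p = 0.14 with an estimated correlation). The replication helicase subunit Mcm6 rose from 39.6 ± 7.81 to 133 ± 14.3 CPM (1.74, SE 0.240, adjusted p = 0.00052) and the cytokinesis kinesin Kif23 from 9.26 ± 3.27 to 36.2 ± 3.31 CPM (1.96, SE 0.276, adjusted p = 0.00057). Among p53 target genes, 1 of 29 was higher and 6 lower (3 and 6 adjusted over the list alone, adjusted p = 0.28). Their list passed as lower by fry (adjusted p = 0.0044) and by camera with length and GC trends removed (median -0.29, adjusted p = 0.039). The cell cycle inhibitor Cdkn1a fell from 514 ± 34.9 to 141 ± 11.6 CPM (-1.87, SE 0.233, adjusted p = 0.00030). Unfolded protein response genes rose, with 8 of 29 higher and none lower (9 and 1 adjusted over the list alone). Their median was 0.33 (adjusted p = 0.00013, but adjusted p = 0.056 with an estimated correlation). Pdia6 rose from 241 ± 28.7 to 830.5 ± 26.4 CPM (1.78, SE 0.132, adjusted p = 1.2e-05) and Hspa5 from 1049 ± 269 to 3044 ± 102 CPM (1.54, SE 0.166, adjusted p = 0.00017).

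NF-kB target genes fell in mTEChi, with 4 of 42 higher and 12 lower (4 and 14 adjusted over the list alone). Their median was -0.50 (adjusted p = 0.0010, but adjusted p = 0.30 with an estimated correlation). The chemokine Cxcl1 fell from 109.9 ± 22.8 to 18.6 ± 7.35 CPM (-2.56, SE 0.311, adjusted p = 0.00026), and Ccl5 from 189 ± 26.4 to 43.6 ± 17.2 CPM (-2.12, SE 0.248, adjusted p = 0.00021). Ccl20, a chemokine for CCR6-bearing cells, fell from 548 ± 54.1 to 154 ± 13.1 CPM (-1.84, SE 0.386, adjusted p = 0.0055). Ltb, the lymphotoxin beta subunit, rose from 24.5 ± 7.12 to 128 ± 36.4 CPM (2.38, SE 0.306, adjusted p = 0.00035). Bcl2a1b had a log2 fold change of -1.27, uncertain because of its near-identical paralogs. Otulin, the deubiquitinase that cleaves linear chains, fell from 333 ± 41.9 to 179.8 ± 10.04 CPM (-0.89, SE 0.164, adjusted p = 0.0027). Its list, LUBAC and its deubiquitinases, had 1 of 10 higher and 4 lower (2 and 4 adjusted over the list alone, adjusted p = 0.12), Rbck1 among the lower ones. By fry the LUBAC list passed with Rbck1 (adjusted p = 0.0064) but not without it (adjusted p = 0.28). Tnfrsf11a (Entrez 21934, chromosome 1, 105780673 to 105849444), the receptor RANK that drives mTEC maturation, rose from 167 ± 26.6 to 306 ± 38.4 CPM (0.87, SE 0.253, adjusted p = 0.028). It did not pass without HOIL-deficient replicate 1 or 3 or control replicate 1 or 3 (adjusted p 0.094, 0.068, 0.13 and 0.095, within 0.00033 to 0.13 over all alternatives). The costimulatory ligand Cd80 (Entrez 12519, chromosome 16, 38457430 to 38495958) was at 24.2 ± 11.01 and 46.0 ± 5.71 CPM (0.92, SE 0.408, adjusted p = 0.13). The chemokine Ccl21a (Entrez 18829, chromosome 4, 42772860 to 42773991), whose near-identical copies make its value uncertain, was at 189.8 ± 39.2 and 165 ± 24.5 CPM (-0.20, SE 0.494, adjusted p = 0.81).

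MHC class II genes rose in mTEChi, with 4 of 22 higher and none lower (6 and 0 adjusted over the list alone). mTEChi were sorted on high MHC class II, and whether the gate bears on these genes was not tested. Their median was 0.38 (adjusted p = 0.033, but adjusted p = 0.35 with an estimated correlation). H2-Aa (Entrez 14960, chromosome 17, 34282744 to 34287823), a class II alpha chain, rose from 7645 ± 299 to 10547 ± 1489 CPM (0.46, SE 0.127, adjusted p = 0.021). Without HOIL-deficient replicate 1 or 3 or control replicate 1 or 3, H2-Aa missed the threshold (adjusted p 0.091, 0.053, 0.058 and 0.065, within 0.00060 to 0.091 over all alternatives). The list missed it without HOIL-deficient replicate 3 or control replicate 1 (median 0.33 and 0.25, adjusted p 0.058 and 0.077). It also missed it with RLE factors (0.057), with upper-quartile factors (0.058) and among males only (adjusted p = 0.053), in 7 of 15 alternatives in all (0.0080 to 0.35). cTEC-associated genes rose in mTEChi, with 8 of 29 higher and 2 lower (9 and 2 adjusted over the list alone). Their median was 0.36 (adjusted p = 0.019, but adjusted p = 0.36 with an estimated correlation). The list had adjusted p = 0.10 with the length and GC trends removed (0.0013 to 0.36 over all alternatives). Foxn1 rose from 68.3 ± 24.3 to 156 ± 16.7 CPM (1.19, SE 0.263, adjusted p = 0.0071), and the chemokine Cxcl12 rose by 1.39 (SE 0.249, adjusted p = 0.0023). Immediate early and dissociation stress genes fell, with 2 of 29 higher and 6 lower (2 and 7 adjusted over the list alone). Their median was -0.65 (adjusted p = 0.0041, but adjusted p = 0.33 with an estimated correlation). The AP-1 subunit Jund fell among them (-1.26, SE 0.196, adjusted p = 0.0010).

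Endothelial genes rose in mTEChi too, with 11 of 20 higher and none lower (14 and 0 adjusted over the list alone). Their median was 1.75 (adjusted p = 1.0e-05, but adjusted p = 0.35 with an estimated correlation). Pecam1, which encodes CD31, rose from 11.9 ± 3.65 to 83.9 ± 43.2 CPM (2.82, SE 0.465, adjusted p = 0.0014). Fibroblast and pericyte genes rose, with 6 of 25 higher and none lower (7 and 0 adjusted over the list alone). Their median was 0.41 (adjusted p = 0.022). They had adjusted p = 0.64 with an estimated correlation and 0.18 by fry (0.0012 to 0.64 over all alternatives). The intermediate filament gene Vim went from 108 ± 17.1 to 369 ± 57.6 CPM (1.77, SE 0.289, adjusted p = 0.0014).

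**Figure D4:**
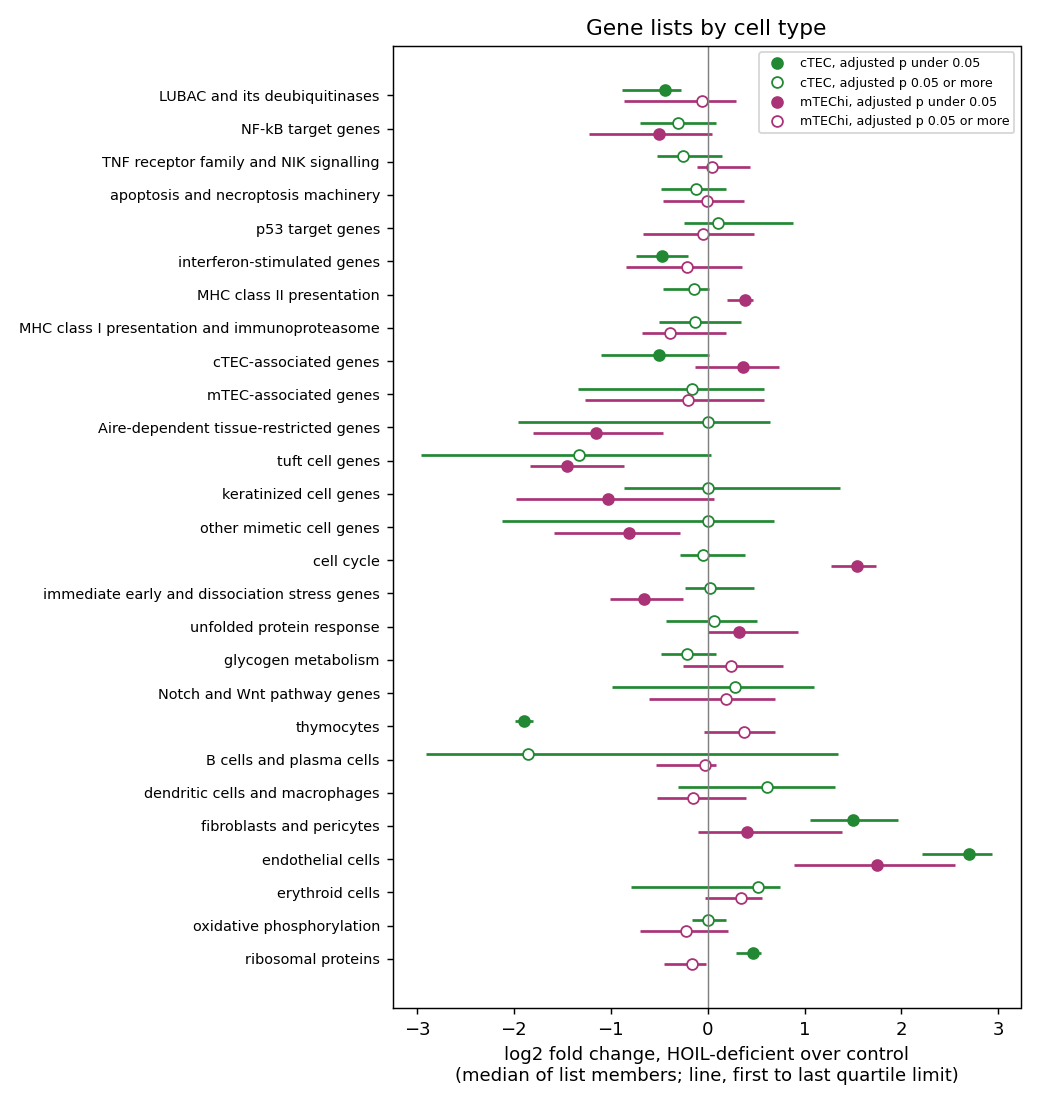
Median log2 fold change of HOIL-deficient over control libraries for 27 gene lists, with cTECs in green, mTEChi in magenta, and a line between the quartiles of the list members. Filled points passed camera with its preset correlation at an adjusted p under 0.05, and the cell cycle median was 1.54 in mTEChi and -0.04 in cTECs, where it was 0.35 without control replicate 1.

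Other lists did not pass in mTEChi by camera with the preset correlation and all libraries. Members called were 5 higher and 12 lower of 45 interferon-stimulated genes (5 and 15 adjusted over the list alone, adjusted p = 0.051). Isg15, a ubiquitin-like modifier, fell among them (-2.32, SE 0.321, adjusted p = 0.00053). That list passed by camera in 6 of 15 alternatives (0.0016 to 0.69 over all). These were the fits without control replicate 1 (adjusted p = 0.0037), HOIL-deficient replicate 2 (0.0090) or both control libraries numbered 1 (0.0056). The others were RLE factors (0.030), upper-quartile factors (0.029) and removal of length and GC trends (0.0016). mTEC-associated genes had 4 higher and 10 lower of 33 (5 and 11 adjusted over the list alone, adjusted p = 0.21), and MHC class I presentation 3 and 6 of 22 (3 and 7, adjusted p = 0.40). Oxidative phosphorylation had 4 and 5 of 33 (6 and 12 adjusted over the list alone, adjusted p = 0.34) and glycogen metabolism 5 and 0 of 25 (5 and 0, adjusted p = 0.090). Glycogen metabolism passed only by fry (adjusted p = 0.0047). Thymocyte genes had 0 and 0 of 23 called by edgeR (0 and 0 adjusted over the list alone, adjusted p = 0.38). They passed as a list without control replicate 1 (adjusted p = 0.048, within 0.026 to 0.97 over all alternatives). Ribosomal proteins had 0 and 1 of 39 (0 and 0 adjusted over the list alone, adjusted p = 0.21). They passed as a list without control replicate 2 (adjusted p = 0.0058, within 0.0058 to 0.88 over all alternatives). The remaining lists had adjusted p of 0.81 for the TNF receptor family with NIK signalling, apoptosis and necroptosis machinery, B and plasma cells, dendritic cells and macrophages, and erythroid cells, and 0.84 for Notch and Wnt pathway genes.

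In mTEChi, 3858 of 19398 genes changed (19.9%; edgeR), 2191 higher and 1667 lower, of which 1082 and 1178 changed at least 2-fold. The balance turned with the scaling, to 1748 higher and 1973 lower with RLE factors, 1708 and 1979 with upper-quartile factors, and 2207 and 2556 with DESeq2. The median of all genes went from -0.03 to -0.11 with either set of factors. The count was 2558 and 2343 without HOIL-deficient replicate 1 or 2, and 1944 and 2279 without control replicate 1 or 3.

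The effects of HOIL deficiency in mTEChi and cTECs were set against each other to show where the populations respond apart. Foxn1, Psmb11, Prss16 and Ly75 moved differently. The mTEChi effect minus the cTEC effect was 1.80 for Foxn1 (SE 0.368, adjusted p = 0.0099), 1.67 for Psmb11 (SE 0.283, adjusted p = 0.0044), 1.99 for Prss16 (SE 0.353, adjusted p = 0.0055) and 1.54 for Ly75 (SE 0.328, adjusted p = 0.012). The list of cTEC-associated genes differed, with 14 of 29 members higher in the difference and none lower (17 and 0 adjusted over the list alone). Its median was 0.91 (adjusted p = 6.5e-09, but adjusted p = 0.14 with an estimated correlation). Cell cycle genes differed as well, with 19 of 42 higher and none lower (30 and 0 adjusted over the list alone). Their median was 1.37 (adjusted p = 2.2e-14, but adjusted p = 0.29 with an estimated correlation). So did thymocyte genes, with 12 of 23 higher and none lower (19 and 0 adjusted over the list alone) and a median of 2.21 (adjusted p = 7.6e-10, but adjusted p = 0.35 with an estimated correlation and 0.069 by fry, within 2.4e-17 to 0.35 over all alternatives). Aire-dependent genes, lower in mTEChi, did not differ detectably from cTECs, where they are scarce (0 and 0 of 54 called by edgeR, median -0.77, adjusted p = 0.36). The endothelial list did not pass in the difference (median -0.49, adjusted p = 0.062), and its median ran from -0.97 to 0.07 over all alternatives. It passed without HOIL-deficient or control cTEC replicate 3 (adjusted p 0.0019 and 0.018), HOIL-deficient mTEChi replicate 2 or 3 (0.018 and 0.033) or control mTEChi replicate 2 (0.031, within 0.00033 to 0.67 over all alternatives). Glycogen metabolism (median 0.44, adjusted p = 0.062) passed without control cTEC replicate 1 or control mTEChi replicate 2 (adjusted p 0.030 and 0.045, within 0.0089 to 0.29). Oxidative phosphorylation (-0.30, adjusted p = 0.17) passed without HOIL-deficient mTEChi replicate 3 or control mTEChi replicate 2 (adjusted p 0.035 and 0.037, within 0.032 to 0.67). Dendritic cells and macrophages (-0.91, adjusted p = 0.22) passed without HOIL-deficient cTEC replicate 1 (adjusted p = 0.048, within 0.048 to 0.51). Differences for Dll4 (0.09), Ccl25 (0.66), Aire (0.84), Fezf2 (0.71), Cd80 (5.32), Tnfrsf11a (-0.08), Ccl21a (1.90) and H2-Aa (0.53) had adjusted p of 0.067 to 0.96. The value of Cd80, at 0 in HOIL-deficient cTECs, depends on the prior count and ran from 1.68 to 5.92 over the alternatives. Without control cTEC replicate 3, Cd80 (5.92, adjusted p = 0.038, within 0.013 to 0.32 over all alternatives) and Ccl21a (2.32, adjusted p = 0.033, within 0.033 to 0.25) passed. Fezf2 passed without HOIL-deficient cTEC replicate 1 (2.61, adjusted p = 0.024, within 0.024 to 1.00).

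The genes with the largest differences had a cTEC group at or near 0, so their fitted values depend on the prior count. Il9r (7.96), Rln3 (7.49), Tex11 (7.47), Slc10a4 (7.38) and Atp8b4 (7.25) were at 0 in HOIL-deficient cTECs only among the 4 groups. In mTEChi, Il9r was at 12.8 ± 2.95 and 32.1 ± 9.56 CPM and Slc10a4 at 8.56 ± 1.61 and 19.6 ± 4.82 CPM. On the lower side, Dmbt1 (-8.57), Cst9 (-8.30), Slurp1 (-7.93), Lgals7 (-7.92) and Rbp4 (-7.36) had 0 or 1 count in control cTECs. In mTEChi, Lgals7, an epidermal galectin, was at 32.6 ± 16.2 and 7.57 ± 2.17 CPM. The call of Rln3 was lost without any single library except control cTEC replicates 1 and 2 (adjusted p up to 0.30), and that of Tex11 without any except those and control mTEChi replicate 2 (up to 0.11). Slurp1 lost its call without HOIL-deficient cTEC replicate 2, control cTEC replicate 2 or 3, HOIL-deficient mTEChi replicate 3, or control mTEChi replicate 1 or 3 (up to 0.15).

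In the difference, 1908 genes were called by edgeR, 1159 higher and 749 lower. The balance turned to 714 and 873 with RLE factors and 651 and 899 with upper-quartile factors, as the median of all genes went from 0.09 to -0.05 and -0.07. The count was 1256 and 949 without control replicate 3 of cTECs or mTEChi, 1172 without control mTEChi replicate 1 and 1182 without HOIL-deficient mTEChi replicate 3. The effects shared genes beyond chance across genes, which are not independent replicates. In both populations 329 genes rose (132.7 by chance, Fisher's exact p = 6.8e-60) and 235 fell (100.3 by chance, Fisher's exact p = 4.2e-37).

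Control mTEChi were compared with control cTECs to place the size of these effects and to check identity. Aire was at 0.839 ± 0.422 CPM in cTECs and 811 ± 159 CPM in mTEChi (9.85, SE 0.559, adjusted p = 7.4e-09), and Fezf2 (8.65), Cd80 (6.57), Tnfrsf11a (4.47) and H2-Aa (1.10) were higher in mTEChi. Psmb11 was at 3772 ± 624 against 82.3 ± 25.6 CPM (-5.52, SE 0.240, adjusted p = 9.8e-10), and Prss16 (-5.63), Ly75 (-5.16), Dll4 (-3.31), Foxn1 (-2.91) and Ccl25 (-2.74) were lower in mTEChi. Rbck1 itself was lower in mTEChi (-0.77, SE 0.249, adjusted p = 0.015), but not with RLE factors (-0.58, adjusted p = 0.057), with DESeq2 (-0.58, adjusted p = 0.052) or without control mTEChi replicate 3 (-0.71, adjusted p = 0.054). Ccl21a was at 98.6 ± 58.2 and 189.8 ± 39.2 CPM (0.95, SE 0.500, adjusted p = 0.11).

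Tissue-restricted genes set the populations furthest apart. Among Aire-dependent genes 53 of 54 were higher in mTEChi and none lower, as they were adjusted over the list alone (median 8.78, or 7.99 with genes at 0 set to their bound, adjusted p = 1.7e-29). Keratinized cell genes were higher in 32 of 32, also adjusted over the list alone (median 6.73, or 6.56 at the bound, adjusted p = 5.7e-15). The gut hormone Pyy was at least 2372-fold higher, Dppa3 at least 1782-fold, Serpinb12 at least 1495-fold and Skint9 at least 1456-fold, all at 0 in control cTECs. Klk1b9 was at least 1133-fold higher, with the uncertainty of its family. The lower genes were led by the transcription factor Klf15 (-6.56), the endothelin receptor Ednrb (-6.24), Frmd6 (-5.97), Tmem169 (-5.85) and Cxcl12 (-5.81). NF-kB target genes were higher in mTEChi, with 28 of 42 higher and 3 lower, both also adjusted over the list alone (median 1.27, adjusted p = 2.2e-06, but adjusted p = 0.11 with an estimated correlation). Thymocyte genes were lower, with 22 of 23 lower, also adjusted over the list alone (median -3.11, adjusted p = 2.4e-08, but adjusted p = 0.38 with an estimated correlation). Cell cycle genes were lower in 31 of 42, also adjusted over the list alone (median -1.12, adjusted p = 4.7e-06, but adjusted p = 0.56 with an estimated correlation). In total 12462 of 19398 genes differed (64.2%; edgeR), 7337 higher and 5125 lower, while the median of all genes went from 0.24 to 0.43 with RLE factors and 0.41 with upper-quartile factors. With the length and GC trends removed the balance turned to 6552 higher and 6630 lower, and the median of all genes was -0.04.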

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

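The interaction contrast, the list tests, the fits with 1 library left out and the counts of splits were planned, while every test of an explanation and the fits without length and GC trends were chosen after the result was seen.

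Genes and gene groups whose response to HOIL deficiency differed between mTEChi and cTECs stand here because the difference itself passed its test. There were 1908 such genes. Of 100 drawn joint splits of the libraries, 2 gave as many or more, the real one included. The highest other split gave 3874 genes. It exchanged the genotypes within 1 cell type, so it added the effects of HOIL deficiency in cTECs and mTEChi. The remaining splits mixed genotypes within at least 1 cell type, which turns genotype effects into spread between libraries. Their counts therefore cannot say whether chance alone gives such a difference. Among genes fixed in advance, the mTEChi effect minus the cTEC effect was 1.80 for Foxn1, 1.67 for Psmb11, 1.99 for Prss16 and 1.54 for Ly75. Among the largest differences it was 7.96 for Il9r, 7.49 for Rln3, 7.47 for Tex11, 7.38 for Slc10a4 and 7.25 for Atp8b4, and -8.57 for Dmbt1, -8.30 for Cst9, -7.93 for Slurp1, -7.92 for Lgals7 and -7.36 for Rbp4. These 10 values depend on the prior count, since each gene had a cTEC group at 0 or 1 count. For the genotype effects the 6 libraries of a cell type make only 10 splits, too few for a share under 0.05: the real split gave 2342 genes in cTECs against at most 2 in another, 3858 against 0 in mTEChi, and 12462 against 0 between the control populations.

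Gene lists whose effects differed were led by thymocyte genes (median difference 2.21), cell cycle genes (1.37) and cTEC-associated genes (0.91). With an estimated correlation these 3 calls were lost (adjusted p 0.35, 0.29 and 0.14), and that of thymocyte genes also by fry (adjusted p = 0.069, within 2.4e-17 to 0.35 over all alternatives). MHC class II genes differed by 0.40 (adjusted p = 0.0020; adjusted p = 0.29 with an estimated correlation), keratinized cell genes by -0.89 (adjusted p = 0.0017; 0.26), immediate early and dissociation stress genes by -0.63 (adjusted p = 0.00025; 0.29), p53 target genes by -0.16 (adjusted p = 0.0072; 0.14, within 0.00033 to 0.14 over all alternatives) and ribosomal proteins by -0.65 (adjusted p = 6.2e-07; 0.57). The ribosomal call was also lost by fry (adjusted p = 0.16) and with length and GC trends removed, where the median was -0.23 (adjusted p = 0.076, within 9.8e-11 to 0.57 over all alternatives). Fibroblast and pericyte genes differed by -0.55 (adjusted p = 0.017; 0.60), a call also lost by fry (adjusted p = 0.33), among males only (0.11) and without HOIL-deficient cTEC replicate 3 (adjusted p = 0.070) or control cTEC replicate 2 (0.11; 1.4e-06 to 0.60 over all alternatives). The median of that list ran from -1.42 to -0.12 over all alternatives. The lists of tuft cells (-0.14, adjusted p = 0.041), other mimetic cells (-0.39, adjusted p = 0.040) and the unfolded protein response (0.32, adjusted p = 0.049) lost their calls in 14, 12 and 14 of 21 alternatives. The estimated correlation was among these for all of them (adjusted p 0.51, 0.29 and 0.29). For tuft cells the lost calls included fits without mTEChi control replicate 1, where the median was 0.12, and without HOIL-deficient mTEChi replicate 2, where it was 0.03. The median of other mimetic cells was -0.61 without control mTEChi replicate 3. That of the unfolded protein response was 0.20 without control mTEChi replicate 1.

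cTEC-associated genes fell in HOIL-deficient cTECs, with a median log2 fold change of -0.51, a call lost with an estimated correlation (adjusted p = 0.27). A smaller share of cTECs, as the whole cause, would lower alike the members at least 4-fold higher in control cTECs than in control mTEChi. That holds only if the cells making up the rest lack their RNA. Fold changes of these members differed from each other (Cochran's Q over n = 21 genes, p = 5.1e-35), from -1.99 for Cd83 to 1.46 for Ackr4. The members were not chosen for absence from the endothelial and fibroblast RNA that rose in the same libraries. Such RNA could also make the falls unequal, so the test cannot speak against a smaller share. The test also treats genes of the same libraries as independent and weights them by the approximate SE. A smaller share of cTECs, alone or together with other changes, stays open. A trend on gene length and GC content is argued against as the whole cause, since the median was -0.36 with these trends removed (adjusted p = 1.2e-07). A change of gene expression within cTECs that lack HOIL is a candidate explanation that stays open as a hypothesis. So do Cre carriage, which goes with genotype in every library, and the smaller amount of thymocyte RNA in the same libraries, neither of which was separated from it.

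Tissue-restricted and mimetic cell genes fell in HOIL-deficient mTEChi. A smaller share of mTEChi would lower Aire, Fezf2, Cd80, Tnfrsf11a and H2-Aa too, but their median log2 fold change was 0.77 and the lowest 0.22. mTEChi were sorted on high MHC class II, so the gate itself may hold up H2-Aa. The listed genes cannot show whether mimetic cells made up a smaller part of the mTEChi, which stays open. Removing the length and GC trends moved the median over the 158 tested members of the 4 lists from -1.11 to -0.97, which argues against these trends as the whole cause. The RNA quality of the control mTEChi libraries cannot be told apart from genotype: their lowest mitochondrial share was 3.19% and the highest of a HOIL-deficient library 1.91%. A change within mTEChi that lack HOIL and Cre carriage, which goes with genotype in every library, stay open and were not separated.

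Endothelial transcripts were higher in both HOIL-deficient populations, although the sort excluded CD31-positive cells. If epithelial cells were fewer and all other cells raised alike, thymocyte genes would have risen too, but in cTECs their median was -1.89 against 2.70 for the endothelial list. In mTEChi the same explanation cannot be told apart, since the thymocyte median was 0.38, or 0.64 without control replicate 1 (adjusted p = 0.048, within 0.026 to 0.97 over all alternatives), and the mean log2 CPM of the endothelial list rose over that of the thymocyte list by 1.19 (95% interval between libraries 0.05 to 2.33), or by 1.01 without that library (-0.28 to 2.29). Endothelial cells or their RNA in the sorted samples are a candidate source that the correlation between genes cannot settle. List members rose and fell together between libraries of the same group, with a mean correlation of 0.43 in cTECs and 0.46 in mTEChi. The 95th percentile over 1000 random lists was 0.0778 and 0.0758. By the estimate of camera, cell cycle genes correlated as much (0.52 in cTECs and 0.53 in mTEChi, against 0.51 and 0.49 for endothelial genes). Correlation therefore does not tell RNA of another cell type from genes that vary together for another reason. A larger endothelial compartment in these thymuses was not tested.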

How the results depend on the processing

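The fits without both control libraries numbered 1 and with length and GC trends removed, and the LUBAC list without Rbck1, were chosen after the data were seen; the other alternatives were planned. Counts of changed genes are given by setting. With limma-voom they were 3870 in cTECs, 6470 in mTEChi, 3468 for the difference and 14766 between cell types. With only the groups compared, 1395 genes changed in cTECs, 4863 in mTEChi and 11835 between cell types. Among males only, 1540 genes changed in cTECs, 2864 in mTEChi, 1030 for the difference and 12731 between cell types, where fewer samples were fitted. With a replicate block (block as a pair of equal numbers) the counts were 1290, 2352 and 1475, and 11937 between cell types. Under the block the differences of p53 target genes (-0.21, adjusted p = 0.086), tuft cell genes (adjusted p = 0.17) and other mimetic cell genes (adjusted p = 0.16) were not called, and those of glycogen metabolism (0.43, adjusted p = 0.033) and oxidative phosphorylation (-0.35, adjusted p = 0.032) were. Between cell types the block ended the call of MHC class I presentation (adjusted p = 0.14) and added that of ribosomal proteins (0.87, adjusted p = 0.00022). Same-number libraries correlated at -0.21 to 0.14. Of 12 such pairs 3 correlated best with their own number, all among the 6 pairs of cell types within a genotype and none between genotypes. With 3 numbers to choose from, such matches also arise by chance, and the labels do not say that a number marks 1 animal. With 1 library left out in turn, counts were 1340 to 2306 in cTECs, 1944 to 3116 in mTEChi, 949 to 2088 for the difference and 11449 to 12351 between cell types. Without both control libraries numbered 1 they were 2642, 2779, 1728 and 11361, and with length and GC trends removed 2600, 3853, 2034 and 13182. Rbck1 kept its call in both genotype comparisons under every alternative, at -3.35 to -2.96 in cTECs and -3.44 to -2.80 in mTEChi. Between control cell types its -0.77 lost the call with RLE factors (-0.58) and DESeq2 (-0.58), and ranged from -0.87 to -0.69 with 1 library left out. Directions turned for H2-Aa between cell types (-0.024 with length and GC trends removed), and for oxidative phosphorylation (-0.92) and ribosomal proteins (-0.78) between cell types with length and GC trends removed. For the LUBAC list between cell types the median was -0.25 in camera and fry alike, and only the direction given by fry differed. Except where fewer samples were fitted, the cause was not tested.

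Of the genes named and called, 69 of 110 in cTECs and 76 of 102 in mTEChi kept their call under every alternative, and none reversed in those comparisons. With an estimated correlation, the Aire-dependent list was the only one of the 28 planned lists to keep its call in a genotype comparison. The depth of 7941217 to 14274333 counts per library limits folds against groups at 0 to lower bounds.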

Other observations

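All tests in this part were chosen after the data were seen, except that of the genes near Foxn1, which was written down before its result was seen.

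Genes of adipocytes were higher in HOIL-deficient cTECs beyond those named above. Of 19 listed genes 13 were higher and none lower, with a median log2 fold change of 4.27. In mTEChi the median was 0.52 and 4 genes were higher and none lower (camera over n = 19 genes, p = 0.10). Fabp4, the fatty acid carrier of fat cells, went from 33.6 to 201 CPM in cTECs (2.57, SE 0.374, adjusted p = 0.00096), and the adipogenic receptor Pparg from 1.37 to 9.71 CPM (2.79, SE 0.494, adjusted p = 0.0032). Both were higher in control and HOIL-deficient mTEChi, Fabp4 at 1390 and 1115 CPM and Pparg at 13.4 and 22.2 CPM. Members not called by edgeR in cTECs included Lpl (-0.08, adjusted p = 0.93) and Dgat2 (-0.79, adjusted p = 0.097). Adipocyte RNA in the sorted HOIL-deficient cTEC samples is a candidate source: the 14 members not seen before the test had a median of 2.80 (8 higher, none lower, camera p = 1.8e-08; p = 0.018 with an estimated correlation). Control mTEChi held 18 of the 19 genes above 1 CPM and control cTECs 7, yet Aire stood at only 0.651 CPM in HOIL-deficient cTECs. No gate of the sort names fat cells, though EpCAM selection would remove them.

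Genes of Schwann cells were higher in both HOIL-deficient populations. The glial transcription factor Sox10 rose by 4.07 in cTECs and 1.99 in mTEChi. Of 20 listed genes, 12 were higher in cTECs and 8 in mTEChi, and none lower in either. Schwann cell RNA may be present in the sorted samples, but the test cannot tell: the 17 members not seen before had a median of 1.43 in cTECs (camera over n = 17 genes, p = 9.6e-16; p = 0.00031 with an estimated correlation) but only 0.82 in mTEChi (p = 0.00015; p = 0.013 with an estimated correlation). Control mTEChi held 19 of the 20 genes above 1 CPM, and EpCAM selection would remove Schwann cells.

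Variants linked to the Cre allele at Foxn1 were considered as a source of changes in both populations. Within 10 Mb of Foxn1, 43 of 389 tested genes changed in cTECs (11.1%, against 12.3% elsewhere) and 81 in mTEChi (20.8%, against 20.1%), with 1-sided Fisher's exact p of 0.798 and 0.375. The test gives no sign of such variants but cannot exclude effects on single genes.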
